A study of Homo sapiens with 19 samples.

How the data were processed

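RiboMethSeq was applied to total RNA of 19 Kasumi-1 libraries. Per the labels' protocols, cells were grown with 20% serum, FBL knockdown was induced with doxycycline at 100 ng/ml, and 100 ng of RNA was hydrolysed in alkali at 95 °C for 12 min to fragments of about 30 nucleotides before small RNA libraries were made. A methyl group on the ribose protects the neighbouring bond from hydrolysis and leaves a gap in the fragment ends.

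Per the submitters' processing notes, the tools used include cutadapt and Bowtie2; versions, reference sequence and settings are not given in the sources used here. The authors deposited a table of end counts for 7000 rRNA positions (1836 of 18S, 5021 of 28S and 143 of 5.8S rRNA), which are whole numbers and not normalized. The authors also deposited score C as a fraction from 0 to 1 for 120 sites, with the guide of each site. Which fragment ends were counted is not stated in the sources used here. Score C is 1 minus the count at the site divided by the mean of the weighted means of 6 positions on either side, with weights falling from 1 to 0.5, and set to 0 where negative. With the count read 1 position after the site, this formula gave the deposited score in 2280 of 2280 pairs of site and library within 1e-09. 117 of these scores were 0. Since the score is a ratio of counts within a library, depth mainly changes its precision, and a site with another methylated nucleotide inside its flanks takes part of that site's change. Of the 120 sites 44 had another listed site within 6 nucleotides.

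Groups were taken from the sample titles. The column names of the mutant libraries conflict with the titles: the libraries titled FBLTri have Dual in the column name, and those titled FBLQua have Tri. The titles were followed, so every value given for FBLTri or FBLQua rests on them. The control clone was also taken from its title, as its column name contains KO like those of the knockout clones. The base at 105 sites came from background knowledge, and 13 sites had only a predicted or unknown guide. The count table gave depth and precision: mean flanking counts per site and library had a median of 928.3 and ranged from 10.3 to 112349, and 95% counting intervals came from 2000 Poisson resamples of the counts. Reads without molecular identifiers are not independent molecules, so these intervals cover counting error only. Replicate pairs were compared by chi-square over positions, which gave 18.6 to 731.3 per position, so no pair agreed within sampling noise.

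Changes in score C were tested with limma 3.58.1 in R 4.3.3, with a coefficient per group, a variance trend, two-sided tests and Benjamini-Hochberg adjustment over the 120 sites at 0.05. The knockdown comparisons used the 14 knockdown libraries, whose 7 groups share an estimate of the spread, and the knockout comparison used all 19 libraries. The test was tried on 20 simulations of 120 sites with the design of the knockdown comparison over both backgrounds. It called 75.5%, 90% and 96.5% of sites changed by 0.05, 0.1 and 0.2, and 3.2% of unchanged sites. All simulated sites and libraries had the same dispersion of counts, so these rates may not hold for the libraries here. The mean score per library was compared by exact permutation. Site lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, over 13 lists; lists of 1 site were only described, and 18S-Cm1440 of a further list was not matched. The share of loss restored is the slope through 0 of the re-expression change on the knockdown loss in the libraries without re-expression. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the counts and plots.

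Named sites followed a rule set before the data were examined: the 20 called sites with the largest change in the knockdown comparison over both backgrounds with the same sign in both, the 8 largest called in each other comparison, the sites of at least 0.1 in the SNORD127 re-expression pair, 18S-Gm1447 and 28S-Gm4469 always, and up to 4 members of each list. Also set then were these alternatives: fits on the compared groups alone, no variance trend, a logit scale, scores recomputed with flanks of 6 or 2 positions, the 10% of sites with the lowest flanking counts left out, library medians made equal, a replicate block, each replicate left out, and an estimated correlation. Scores not set to 0, predicted positions left out and the library with 20.79% of its counts at 1 position left out of the fit were added after seeing the data.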

Results

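Ribose methylation of ribosomal RNA was measured by RiboMethSeq in 19 libraries from Kasumi-1, an established acute myeloid leukaemia cell line. Fibrillarin (FBL) is the methyltransferase of the box C/D small nucleolar ribonucleoproteins, in which a guide RNA (SNORD) selects the nucleotide whose ribose is methylated. The libraries fell into 11 groups. There were 7 knockdown groups of 2 libraries each: control knockdown (KD) and FBL KD without re-expression, control KD and FBL KD with an empty vector, and FBL KD with wild-type FBL or with the mutants named FBLTri and FBLQua in the sample titles, from which the column names differ. The other 5 libraries came from SNORD127 knockout clones C1 and C34, a control clone, and clone C1 with an empty vector or with SNORD127. The title of the control clone calls it a control knockout clone, and its column name has the form of those of the knockout clones. Its use as a control therefore rests on the title. The measurement is score C, which compares the number of fragment ends next to a nucleotide with the numbers around it and approaches 1 where all molecules are methylated. It was deposited for 120 sites, of which 47 are in 18S, 71 in 28S and 2 in 5.8S rRNA. Site numbers are rRNA positions in the older 28S numbering, so no genome coordinates apply.

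Libraries held 5533150 to 18835537 end counts. The 4 knockdown libraries without re-expression were the shallowest, at 5533150 to 9021579 end counts. Across sites and libraries the 95% counting interval of score C had a median half-width of 0.0151 and a largest of 0.392. Replicate 2 of control KD with empty vector stood apart, with 20.79% of its counts at position 15 of 28S, against 0.24 to 2.72% in the other libraries. In that library 18S-Cm174 scored 0, against 0.825 in replicate 1. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. The column names of the 2 FBL KD libraries without re-expression contain shFBL1 and shFBL2, and those of the FBL KD libraries with a vector shFBL4. The labels do not say whether these mark hairpins; if so, the 2 libraries are not plain replicates and the hairpin goes together with the background. FBL and SNORD127 transcripts are not part of an rRNA end count, so the knockdown and knockout could not be checked at the targeted gene.

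FBL KD lowered score C over most of the rRNA. The mean over the 120 sites was 0.877 ± 0.011 (SD, n = 4) in the control KD libraries and 0.753 ± 0.037 (SD, n = 4) in the FBL KD libraries, each set holding 2 libraries without re-expression and 2 with empty vector. The difference of 0.124 had p = 0.0286 in a two-sided exact permutation test, the smallest p that the 70 arrangements allow. These arrangements exchange libraries across the backgrounds. Exchange within each background would leave fewer arrangements and a larger smallest p. Site by site, 86 of the 120 sites fell and 2 rose (limma, adjusted p under 0.05). The 2 sites that rose, 18S-1410 and 28S-1339, are positions with only a predicted guide. 28S-1339 was not called higher with empty vector alone, where 0 of the 71 sites in 28S were. Over both backgrounds 59 of 71 sites in 28S fell, with a median change of -0.153. In 18S 26 of 47 sites fell, with a median change of -0.044. The median score of the libraries moved by -0.118, and when library medians were made equal 39 sites were called lower and 57 higher. The direction of the moderate changes thus holds on the deposited scale and not relative to the median site. Making medians equal takes their shift out of every site, also where that shift comes from the knockdown itself. Such splits therefore cannot tell a loss at most sites from a shift of whole libraries.

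The most reduced sites lay mainly in 28S rRNA. 28S-Cm1868, guided by SNORD48 according to the deposited annotation, fell by 0.699 over both backgrounds (SE 0.028, adjusted p = 5.23e-08 by limma). Without re-expression its score was 0.727 ± 0.045 in control KD and 0.066 ± 0.035 in FBL KD (SD, n = 2). The change was -0.590 (SE 0.018) at 28S-Am2388 (SNORD68) and -0.562 (SE 0.034) at 28S-Gm2863 (SNORD50A). 18S-Gm1447, the SNORD127 site, fell by 0.510 (SE 0.047, adjusted p = 9.43e-06 by limma) and was the most reduced 18S site. 28S-Um2402 fell by 0.560, and its score was 0 in all FBL KD libraries. Scores below 0 are set to 0 in the deposited values, which removes the spread there; without that step the change at 28S-Um2402 was -1.13 (SE 0.038). The flanks of this site include position 2401 of 28S, the most counted position in both FBL KD libraries without re-expression and in replicate 2 of control KD. 28S-Gm4020, 28S-Cm3787, 28S-Am1313, 28S-Cm2848, 28S-Gm1303, 28S-2811, 5.8S-Gm75 and 28S-Am2774 fell, with changes from -0.412 to -0.301. 28S-Gm4588, 28S-Gm1509, 28S-Gm3723, 28S-Um4590, 28S-Am3739, 28S-Gm1747 and 28S-Cm3680 fell, with changes from -0.296 to -0.240. 28S-Gm4469, which background knowledge assigns to the stand-alone methyltransferase FTSJ3, changed by -0.003 (SE 0.004, 95% interval -0.012 to 0.006) and was not called.

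**Figure D1:**
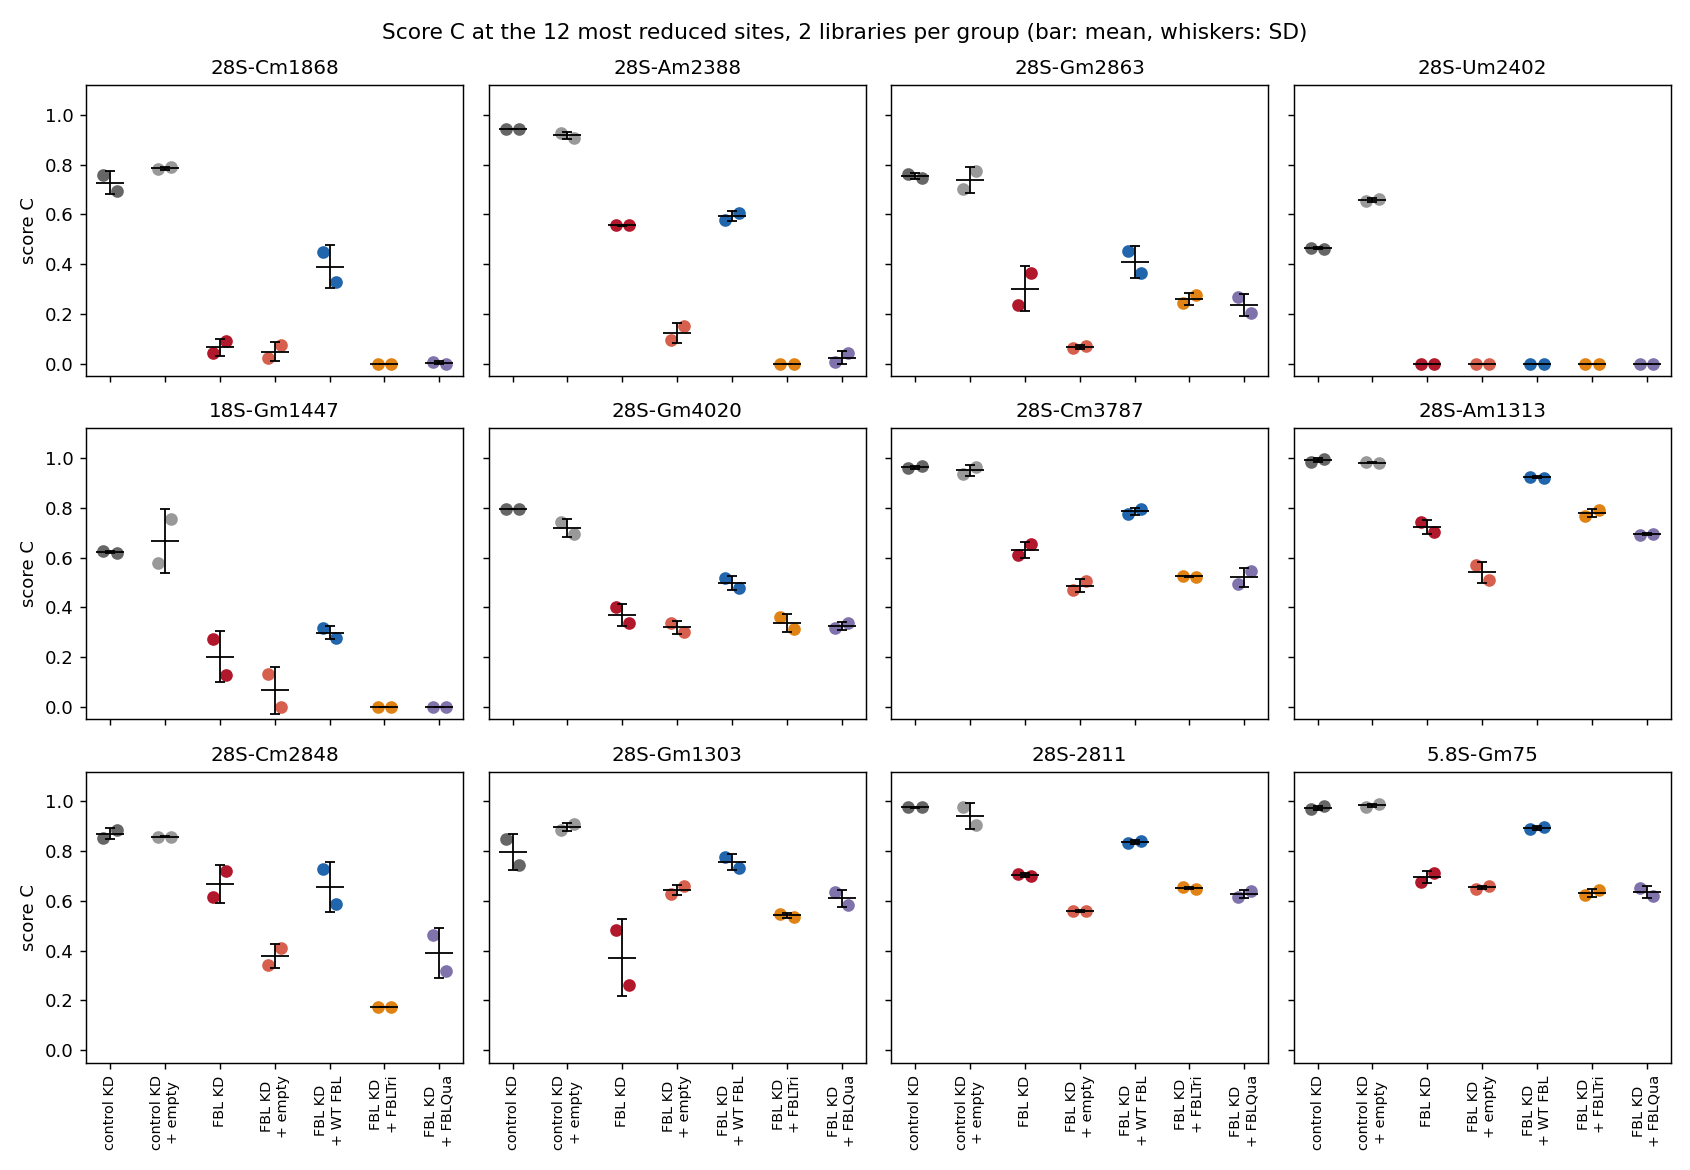
Score C (vertical axis, no unit) at the 12 sites with the deepest loss on FBL knockdown, in the 7 knockdown groups; each point is 1 of the 2 libraries of a group, the bar is the mean and the whiskers are the SD. 28S-Cm1868 lies at 0.727 in control KD and 0.066 in FBL KD, and 28S-Um2402 is at 0 in all FBL KD groups, where scores below 0 are set to 0.

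Sites were grouped by lists fixed before the data were examined. All 10 sites guided by snoRNAs hosted in GAS5, a non-coding host gene of box C/D snoRNAs, fell, with a median change of -0.071; the change was -0.162 at 28S-Am391, -0.137 at 28S-Gm4593, -0.118 at 28S-Am1521 and -0.109 at 28S-Cm4032. Of the 5 RPL13A-hosted sites 4 fell, led by 28S-Um2824 (-0.162) and 28S-Am1511 (-0.107), then 18S-Um1326 (-0.044) and 18S-Gm1328 (-0.025). Of the 8 SNHG1-hosted sites 4 fell: 28S-Am389 (-0.237), 28S-Am3804 (-0.093), 18S-Cm1391 (-0.083) and 18S-Am1383 (-0.054). Around the peptidyl transferase centre of 28S, where peptide bonds are formed, 7 of 13 sites fell, with 28S-Gm4198 at -0.191, 28S-Um4276 at -0.153, 28S-Gm4464 at -0.116 and 28S-Um4197 at -0.069. By methylated base, 28 of 33 Am, 17 of 23 Cm, 24 of 29 Gm and 14 of 20 Um sites fell. 18S-Um1442, 5 nucleotides from the SNORD127 site, fell by 0.178. Adjusted over the list alone, the counts of these host-gene, peptidyl transferase centre and base lists were the same.

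Camera, which asks whether a list moved more than the other sites, gave adjusted p = 0.000951 for 28S sites (more negative) and adjusted p = 0.000951 for 18S sites (less negative). With an estimated correlation the adjusted p was 0.0702 for 28S and 0.0829 for 18S, so neither list was called. Sites at 0.9 or more in the SNORD127 control clone were called as more negative (adjusted p = 0.00236, and adjusted p = 0.0922 with an estimated correlation), and those under 0.9 as less negative (adjusted p = 0.00236, and adjusted p = 0.111 with an estimated correlation). In the latter list the test differs in sign from the mean (-0.170) and the median (-0.107), which lie below those of the former (-0.108 and -0.078). The 9 other lists tested, the host-gene, peptidyl transferase centre, base and 5.8S lists, had adjusted p from 0.354 to 0.855.

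The knockdown effect was measured in 2 backgrounds that share no library. Without re-expression 71 sites fell and 2 rose, and with empty vector 81 fell and 1 rose (limma, adjusted p under 0.05). The splits were 28 lower and 51 higher, and 34 lower and 56 higher, once library medians were made equal. 66 sites fell in both, where independent lists would share 47.9, and the changes had a Pearson r of 0.78 across sites, which are not independent replicates. The effect itself differed at 36 sites, a difference that cannot be separated from that of the shFBL number, being more negative with empty vector at 30 and less negative at 6. At 28S-Am2388 the effect with empty vector minus that without was -0.408 (SE 0.035, adjusted p = 0.000106 by limma), the score reaching 0.123 ± 0.040, against 0.556 ± 0.002 without re-expression (SD, n = 2). 28S-Cm2848, 28S-Gm3723 and 28S-Gm2863 had differences of -0.278, -0.248 and -0.217, and 28S-Am1521 of 0.114. The count fell to 23, 22 and 20 without replicate 1 or 2 of FBL KD with empty vector or replicate 2 of control KD, and to 15 (8 lower, 7 higher) on a logit scale. It split into 12 lower and 19 higher with library medians made equal.

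**Figure D2:**
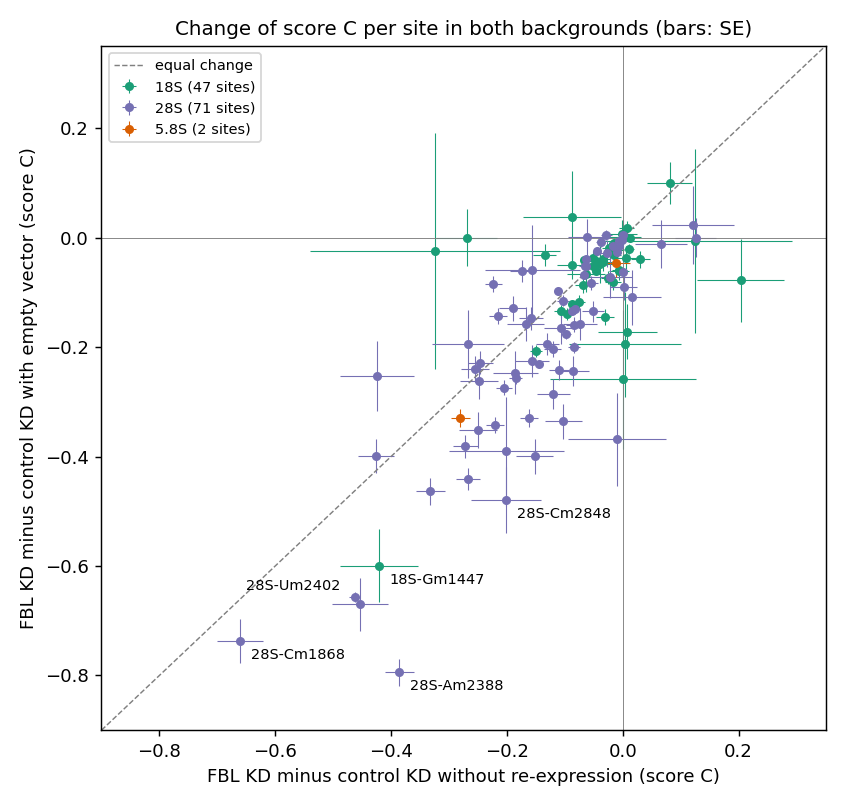
Change of score C on FBL knockdown at each of the 120 sites without re-expression (horizontal axis) and with empty vector (vertical axis), coloured by rRNA, with SE bars and a dashed line of equal change. On the deposited scale most 28S sites lie below the line, and 28S-Am2388 shows the largest of the called differences, at -0.408.

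Re-expression of wild-type FBL in FBL KD cells raised score C at 69 sites and lowered it at 1, 18S-Am27, relative to empty vector (limma, adjusted p under 0.05). 28S-Am2388 rose by 0.470 (SE 0.025, adjusted p = 9.87e-07), reaching 0.593 ± 0.019 (SD, n = 2). 28S-Am1313 rose by 0.382, 28S-Gm2863 by 0.342, 28S-Cm1868 by 0.341, 28S-Cm3787 by 0.299, 28S-Cm2848 by 0.279, 28S-Gm1509 by 0.278 and 28S-2811 by 0.277. With the compared groups alone 28S-Cm2848 was not called, its adjusted p by limma ranging from 0.00044 to 0.0513 over the alternatives. Across the 120 sites the slope of the gain on the loss seen in the separate libraries without re-expression was 66.1% (60.3 to 68.5% when each library was left out in turn). That loss was the smaller of the 2, with a mean change of -0.1017 against -0.1469 with empty vector. Among the 56 sites that lost at least 0.1 with empty vector, the median share regained was 67.9%. Here loss and gain share the FBL KD libraries with empty vector, so chance values in them enter both. 28S-Um2402 stayed at 0 on the deposited scale; without the setting to 0 it rose by 0.430 (SE 0.054, adjusted p = 6.62e-05 by limma), from -0.701 ± 0.038 to -0.271 ± 0.035 (SD, n = 2). That scale was chosen after seeing the data. Making library medians equal, which had moved by 0.096, left 20 sites called higher and 50 lower.

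Cells with wild-type FBL still differed from control KD cells with empty vector at 36 sites, 35 lower and 1 higher (limma, adjusted p under 0.05). 28S-Um2402 was lower by the deposited score, at -0.657 (SE 0.010), 28S-Cm1868 at -0.396 (SE 0.040), 18S-Gm1447 at -0.370 (SE 0.067), 28S-Gm2863 at -0.329 and 28S-Am2388 at -0.325. The call of 18S-Gm1447 was lost with the compared groups alone and on a logit scale, its adjusted p by limma reaching 0.126. 28S-Gm4588 (-0.308), 28S-Am4560 (-0.302) and 28S-Gm3723 (-0.286) followed. The call of 28S-Gm4588 was lost without replicate 2 of the control (-0.228) or replicate 1 or 2 of wild-type FBL (-0.294 and -0.322), and also with no variance trend, flanks of 2 nucleotides, equal library medians or the compared groups alone. That of 28S-Am4560 was lost without replicate 1 or 2 of the control (-0.265 and -0.338) or replicate 1 of wild-type FBL (-0.247), and with the compared groups alone. Equal library medians gave 13 sites lower and 25 higher.

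Across the sites as a whole the FBL mutants gave no such recovery, though they raised single sites that had fallen on knockdown. 28S-Am1313 rose over empty vector by 0.238 with FBLTri and 0.154 with FBLQua, against 0.382 with wild-type FBL. At 28S-Gm1509 the rises were 0.191 and 0.116, against 0.278. Relative to empty vector FBLTri raised 20 sites and lowered 24, and FBLQua raised 9 and lowered 14 (limma, adjusted p under 0.05). The slope on the loss was -0.3% for FBLTri (-2.6 to 2.1% with each library left out) and 2.8% for FBLQua (0.5 to 5.2%). The median share regained at the 56 sites was 6.2% and 8.7%. Loss and gain share the empty-vector libraries in these medians, and the share to be found with no recovery was not computed. Against wild-type FBL, 75 sites were lower and 0 higher with FBLTri, and 71 lower and 1 higher with FBLQua (limma, adjusted p under 0.05). 28S-Am2388 differed from wild type by -0.593 with FBLTri (SE 0.025, adjusted p = 1.98e-07) and by -0.568 with FBLQua (SE 0.025, adjusted p = 8.38e-07). 28S-Cm1868 was lower by -0.389 and -0.385, 28S-Cm2848 by -0.485 and -0.267 (the latter not called with the compared groups alone, adjusted p by limma from 0.00037 to 0.0727 over the alternatives), 28S-Cm3787 by -0.262 and -0.265, 5.8S-Gm75 by -0.261 and -0.258, and 18S-Am159 by -0.285 and -0.223. 18S-Gm1447 was lower by -0.297 with either mutant, having a score of 0 in all 4 mutant libraries; with scores not set to 0 the changes were -0.447 and -0.343, and FBLTri differed from empty vector by -0.216 (adjusted p = 0.0424 by limma). 28S-Am389 was lower by -0.255 with FBLTri and -0.189 with FBLQua, and 28S-Am1313 by -0.143 and -0.228. After library medians were made equal the splits were 24 lower and 42 higher for FBLTri, and 23 lower and 43 higher for FBLQua.

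**Figure D3:**
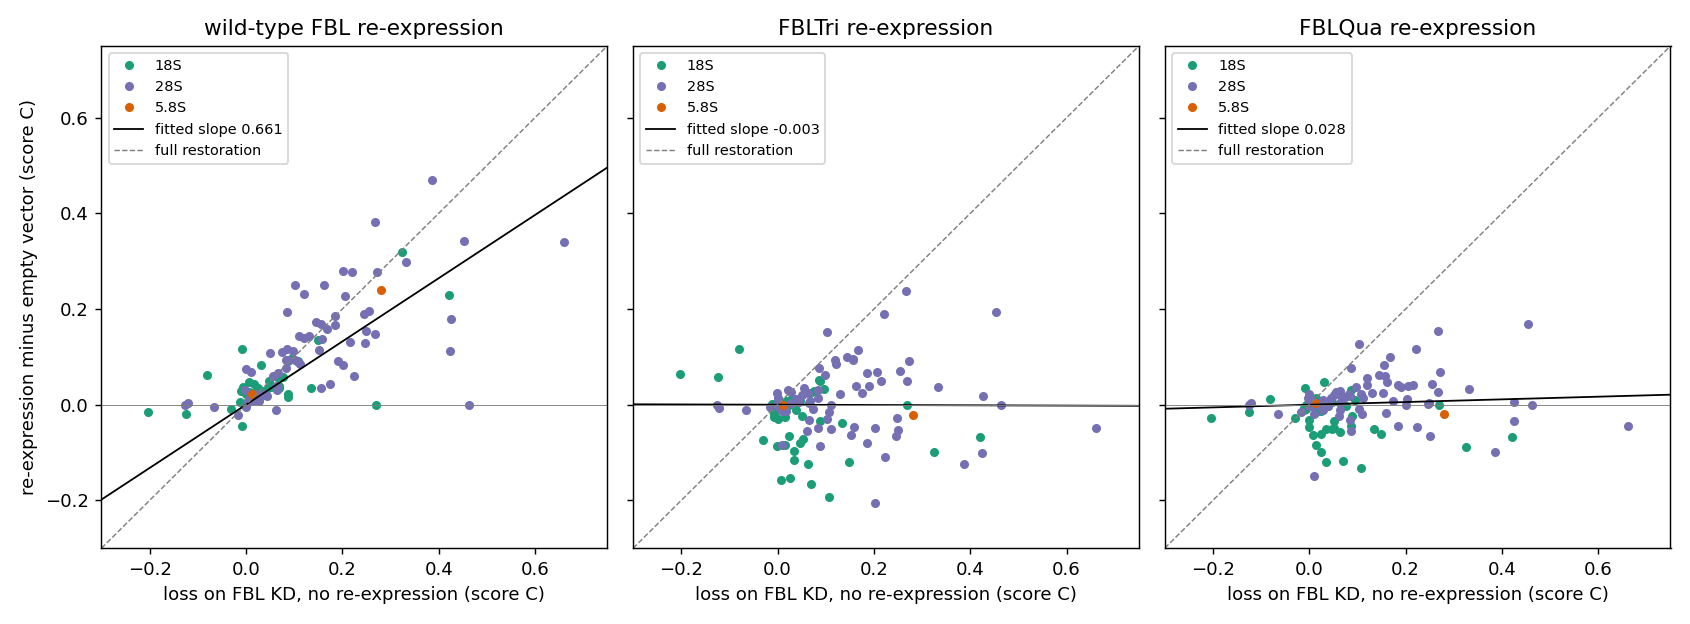
Gain of score C over empty vector on re-expression (vertical axis) against the loss on FBL knockdown in libraries without re-expression (horizontal axis) at the 120 sites, for wild-type FBL, FBLTri and FBLQua. The solid line is the fitted line through 0. The dashed line, labelled full restoration, marks a gain equal to that loss. The loss with empty vector was larger (mean change -0.1469 against -0.1017), so a site on the dashed line need not have reached its control. The slope of the solid line is 0.661 for wild-type FBL, -0.003 for FBLTri and 0.028 for FBLQua.

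Relative to empty vector the mutants changed sites in both directions. FBLTri lowered 24 sites and raised 20, and FBLQua lowered 14 and raised 9 (limma, adjusted p under 0.05). Of the 18S sites FBLTri lowered 14 and raised 4, and of the 28S sites it lowered 10 and raised 16; for FBLQua these were 11 and 2, and 3 and 7. 18S-Am159 (SNORD45 guides) fell by 0.193 with FBLTri (SE 0.011, adjusted p = 6.98e-06) while its change with FBLQua was -0.132 (adjusted p = 0.000155). At 18S-Um116 the changes were -0.165 and -0.117. 28S-Am1313 rose by 0.238 and 0.154, 28S-Gm2863 by 0.193 and 0.169, 28S-Gm1509 by 0.191 and 0.116, and 28S-Cm1327 by 0.153 and 0.126. 18S-Um799 changed by -0.158 and -0.063, 18S-Am512 by -0.115 and -0.119, and 28S-Am2388 by -0.123 and -0.099, the last not called with scores not set to 0 (adjusted p = 0.0656 by limma) or with flanks of 2 nucleotides (-0.054). 28S-Cm2848 changed by -0.206 with FBLTri and by 0.0127 with FBLQua, where it was not called, and the mutants were not called as different there (-0.2184, adjusted p = 0.0584 by limma). Its FBLTri call was lost on a logit scale and without replicate 1 or 2 of FBLTri (-0.206 both times) or of the empty vector (-0.239 and -0.172). The FBLQua call of 28S-Gm2863 was lost without replicate 1 or 2 of FBLQua (0.138 and 0.199) or of the empty vector (0.163 and 0.174), and its FBLTri call without replicate 2 of FBLTri (0.177) or replicate 1 or 2 of the empty vector (0.188 and 0.198). With FBLQua, 28S-Cm1327 was not called without its replicate 1 (0.1) or either empty vector (0.134 and 0.119), nor 28S-Am2388 without its replicate 1 (-0.080) or replicate 2 of the empty vector (-0.070). Over the 76 sites with no other listed site within 6 nucleotides, the mean 18S change minus the mean 28S change was -0.013 for FBLTri and -0.021 for FBLQua, against -0.045 and -0.043 over all sites. With wild-type FBL it was -0.081 and -0.076, but there the mean change was a rise in both, 0.042 in 18S and 0.118 in 28S over all sites. The calls of the mutants against empty vector depend on the scale and on single libraries: on a logit scale 10 and 7 sites were called. Among the named sites the FBLTri calls of 18S-Am159, 28S-Gm1509, 18S-Um799 and 28S-Cm1327 were also lost under at least 1 of the alternatives. Those of 28S-Am1313 and 18S-Um116 were kept. FBLTri calls fell to 28, 29 and 28 without its replicate 2 or replicates 1 or 2 of the empty vector, and FBLQua calls fell to 15 without its replicate 1 and to 0 in a fit of its own libraries and the empty vector alone. Under equal library medians FBLQua was called lower at 13 sites and higher at 13.

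FBLTri and FBLQua differed from each other at 10 sites, 6 lower and 4 higher with FBLTri (limma, adjusted p under 0.05). 18S-Um799 was lower by -0.095, 28S-Gm3878 by -0.062, 18S-Am159 by -0.061, 18S-Um1442 by -0.059, 18S-Am99 by -0.054 and 18S-Am166 by -0.046, and 28S-Am1313 and 28S-Gm1509 were higher by 0.085 and 0.075, with adjusted p from 0.0167 to 0.0467. The count was 0 without replicate 1 or 2 of FBLTri, 2 and 1 without replicate 1 or 2 of FBLQua, and 0 on a logit scale. It was 6 with library medians made equal, 5 lower and 1 higher.

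SNORD127 carries the guide for 18S-Gm1447 in the deposited annotation, and the knockout clones address which sites depend on it. 18S-Gm1447 scored 0.178 in clone C1 (95% counting interval 0.143 to 0.213), 0.254 in clone C34 (0.223 to 0.282) and 0.543 in the control clone (0.520 to 0.564), over mean flanking counts of 2842.4, 3298.2 and 3563.8. The difference of -0.327 (SE 0.080) was the largest of the 120 sites, and the next in size was 0.065. It was lower in 2 of 2 knockout clones, but with 1 control library, assumed to vary like the other groups, it did not pass the correction: limma called 0 sites, with 3 at an unadjusted p under 0.05, and 18S-Gm1447 had adjusted p = 0.301. Across the alternatives its adjusted p ranged from 0.080 to 1. 18S-1705 was called with the knockdown libraries left out of the fit, and 28S-Um2402 with the predicted positions left out, both named after their values were seen. Their changes were small beside that of 18S-Gm1447, at -0.026 and 0.036. 18S-1705 scored 0 in both knockout clones and 0.026 in the control clone.

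Re-expression of SNORD127 in clone C1 brought 18S-Gm1447 to 0.951 (0.942 to 0.960), against 0.061 (0.018 to 0.102) with empty vector. This was above the 0.543 of the control clone and above the highest score in a control KD library, 0.756. The difference of 0.890 from empty vector ranked 1 of 120 by size. The only other site with a difference of at least 0.1 was the predicted position 18S-1680, with 0.209 against 0. Each condition had 1 library, so no test was made and the intervals cover counting error only. 18S-Um1442 scored 0.913 with SNORD127 and 0.953 with empty vector, a change of -0.041, or -0.027 with flanks of 2 nucleotides, which leave out the count read for 18S-Gm1447.

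**Figure D4:**
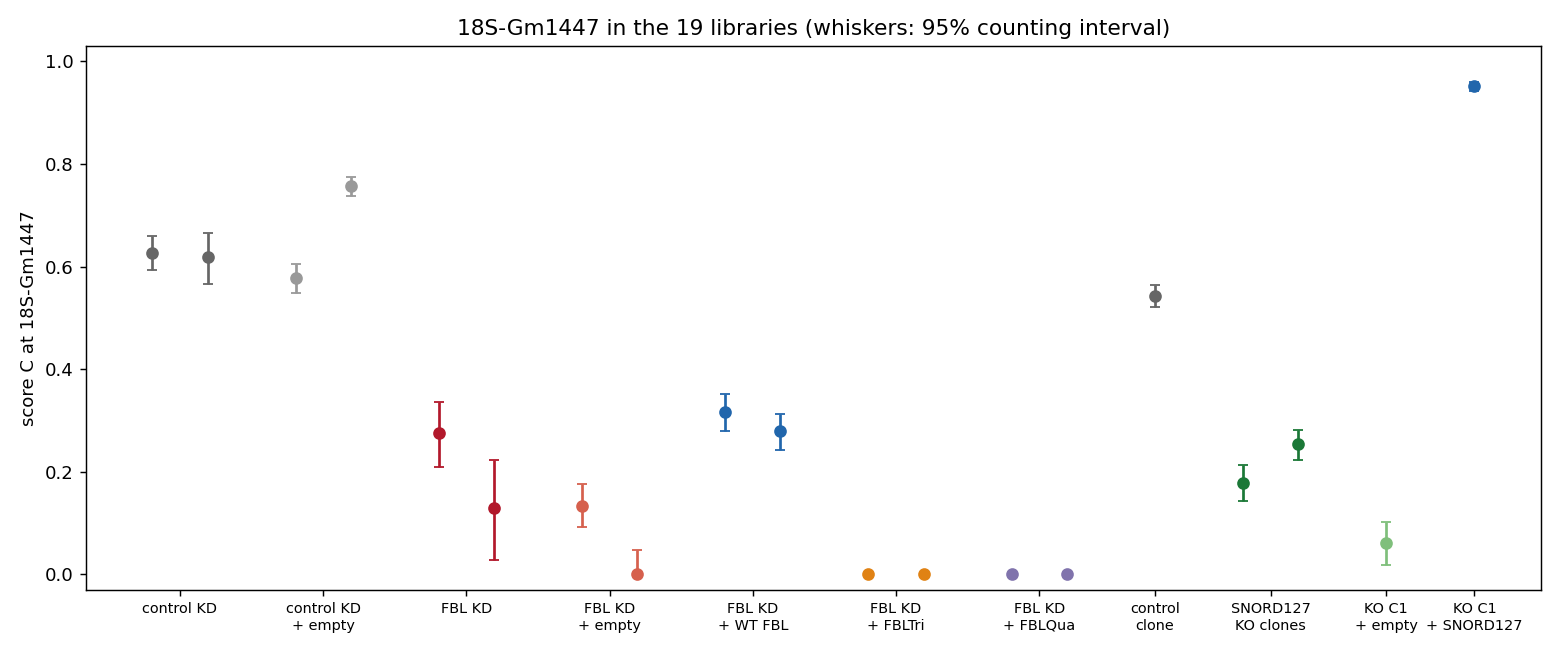
Score C of 18S-Gm1447 (vertical axis, no unit) in each of the 19 libraries by group, with whiskers for the 95% counting interval. It is 0.951 in clone C1 with SNORD127 and 0 in all 4 libraries with an FBL mutant, where scores below 0 are set to 0.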

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

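Of the tests in this part, those of counting error with a widened bound and of the library with 20.79% of its counts at 1 position were chosen after the result was seen.

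Among the splits of the 8 control KD and FBL KD libraries into 4 and 4, fitted with no background term, 1 of the 35 gave as many called sites as the real split, which was the real split itself. It called 73 sites and the highest of the other splits, that by background, called 3. All other splits mix FBL KD and control KD libraries, which adds any real difference to their spread, so few calls there say little. The splits also do not keep the backgrounds apart. Ranking 1 of 35 makes chance assignment of libraries less likely as the source of the knockdown calls but does not exclude it.

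The knockdown effect differed between the backgrounds at 36 sites by an interaction contrast. At the named sites the effect with empty vector minus that without re-expression was -0.408 at 28S-Am2388, -0.278 at 28S-Cm2848, -0.248 at 28S-Gm3723, -0.217 at 28S-Gm2863, -0.194 at 28S-Um2402, -0.175 at 28S-Am1313 and -0.168 at 28S-Gm1747. It was -0.131 at 28S-Cm3787, -0.122 at 28S-Gm1509, -0.109 at 28S-2811, -0.084 at 28S-Am3804, -0.083 at 28S-Um2824, -0.079 at 28S-Gm4593, -0.069 at 28S-Cm3680, -0.058 at 18S-Um1442 and -0.048 at 28S-Am1511. It was 0.114 at 28S-Am1521, 0.103 at 18S-Cm1391 and 0.027 at 18S-Am1383. Since 28S-Um2402 was set to 0 in all FBL KD libraries, its value is only the difference of the 2 control groups; with scores not set to 0 it was -0.457 (SE 0.076).

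Since the 36 sites were picked from 120, counting error of the shallower libraries was tested with a bound widened for that number, 3.53 counting standard errors. 31 of the 36 differences exceeded it, which argues against counting error alone as the source of the whole pattern. Counting error stays open at the other sites. The 95% counting interval, the bound set beforehand and without that widening, was exceeded by 36 of the 36. Over all 120 sites it was exceeded at 65, where counting error would give 6. These bounds cover counting error only, while replicate pairs differed by more than sampling noise, so other noise is not addressed. Without the control library that held 20.79% of its counts at 1 position, 25 of the 36 sites stayed called with the same sign, which argues the same way against that library. FBL was not measured here, so a stronger loss of it in the cells with a vector was not tested. The background goes together with the preparation and with the shFBL number in the column names, which may mark the hairpin. The count was 23, 22 and 20 without replicate 1 or 2 of FBL KD with empty vector or replicate 2 of control KD.

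A signal outside the 120 listed sites was found at the unlisted position 28S-3606. Among 261 unlisted positions with a score of at least 0.75 in all 5 control libraries and a mean flanking count of at least 50, limma called 1 lower and 0 higher on FBL KD, a choice of positions that favours falls. 28S-3606 changed by -0.252 (SE 0.019, adjusted p = 1.15e-05), from 0.961 ± 0.007 to 0.798 ± 0.009 without re-expression and from 0.987 ± 0.005 to 0.646 ± 0.017 with empty vector (SD, n = 2). Wild-type FBL changed it by 0.204 relative to empty vector (adjusted p = 0.00277) and FBLTri by -0.168 (adjusted p = 0.0161), while FBLQua changed it by -0.058 (adjusted p = 0.998).

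The change was 94.8 counting standard errors, over flanking counts of at least 5593, where a bound widened for picking 1 of 261 positions is 3.73, which argues against counting error. With flanks of 2 nucleotides it was -0.212, which argues against counts farther away as its source. An FBL-dependent protection of this nucleotide, structure of the RNA or another modification nearby was not tested.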

How the results depend on the processing

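Of 1536 values of named sites under the alternatives, 1411 kept their direction and side of the threshold, 113 lost the call, 1 gained it and 11 changed direction. The 11 all came from making library medians equal in the comparison of FBL KD with control KD: 28S-Gm4469 became 0.115, 28S-Gm4464 0.002, 28S-Um4197 0.049, 28S-Am3804 0.025, 18S-Cm1391 0.035, 18S-Am1383 0.064, 28S-Am1521 4e-04, 28S-Cm4032 0.009, 28S-Am1511 0.011, 18S-Um1326 0.074 and 18S-Gm1328 0.093, as the setting adds the shift of the medians to each site. The counts of called sites for FBL KD against control KD, wild-type FBL against empty vector or control, and either mutant against wild-type FBL stayed within 1.5 times of the main count under all alternatives run. Their direction did not stay the same: with library medians made equal, the more frequent direction of the called sites was reversed in each of these comparisons. On a logit scale the difference between backgrounds was called at 15 sites, FBLTri against empty vector at 10, FBLQua at 7 and FBLTri against FBLQua at 0. In fits of the compared groups alone FBLQua against empty vector gave 0 and the mutants against each other 1. Leaving out each replicate gave 20 to 40 sites for the difference between backgrounds, 28 to 30 for FBLTri, 15 to 21 for FBLQua and 0 to 2 between the mutants. With library medians made equal the mutants differed at 6 sites, 2 site lists were called, and the restored share became 0.537, 0.027 and 0.056 for wild-type FBL, FBLTri and FBLQua. With scores not set to 0 it was 0.587 for wild-type FBL and -0.033 for FBLTri. Leaving out each replicate gave 0.603 to 0.685 for wild-type FBL. With an estimated correlation 0 of the 4 site lists stayed called. The knockout comparison called 1 site with the knockdown libraries left out of the fit and 1 with the predicted positions left out; the cause of these changes was not tested. Replicate numbers were not taken to pair the libraries: same-numbered libraries of 21 group pairs deviated with r from -0.23 to 0.69 (median 0.16), over 0.1 in 12 and not in all. A replicate block left 87 sites for FBL KD against control KD, 33 for the difference between backgrounds and 5 between the mutants, and named sites not called with it were 28S-Gm2863 for FBLQua against empty vector, 28S-Gm4588 for wild-type FBL against control, and 28S-Am1313, 28S-Gm3878, 18S-Am99 and 18S-Am166 between the mutants. Depth limits sites with low flanking counts, the lowest being 10.3.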

Other observations

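The test of the library-wide shift in this part was chosen after the result was seen, as were the camera tests of the mutants.

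The 23 sites called with FBLQua relative to empty vector were among the 44 called with FBLTri: 14 sites were called lower with both, 9 higher with both and 0 in opposite directions, where independent lists would share 2.8 and 1.5. Both comparisons use the same empty-vector libraries. Their changes had r = 0.863 across sites, against 0.485 in simulations with no effect, and a covariance of 0.0032 against 0.000842. With each mutant set against a different empty-vector library r was 0.703 and 0.658.

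The mutants tended to lower 18S sites and to raise 28S sites relative to empty vector: the mean 18S change minus the mean 28S change was -0.045 for FBLTri and -0.043 for FBLQua. With wild-type FBL it was -0.076, and -0.081 over sites with no listed site within 6 nucleotides. Wild-type FBL raised both sets, with mean changes of 0.042 in 18S and 0.118 in 28S, so its difference reflects a larger gain in 28S. Camera gave p = 0.00324 for 18S and p = 0.00286 for 28S with FBLTri, and p = 9.74e-05 and p = 7.85e-05 with FBLQua; with an estimated correlation these were p = 0.0432, p = 0.0178, p = 0.013 and p = 0.00436, in limma fits of the 14 knockdown libraries.

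A library-wide shift of score C alone would move sites one way, whereas 20 sites were called higher with FBLTri beside 24 lower. These calls are the pattern itself, so they are no test independent of it. Chance values particular to each empty-vector library would leave little agreement once those libraries are split, whereas the smaller r was 0.66. Values common to both empty-vector libraries would survive the split, so they stay open. Flanks shared with another listed site stay open: over sites with none within 6 nucleotides the 18S minus 28S difference was -0.013 for FBLTri (SE 0.017 across sites, permutation p = 0.461) and -0.021 for FBLQua (SE 0.011, permutation p = 0.0912), against -0.093 and -0.075 over sites with a neighbour. It stayed below 0 with each library left out, the bound set beforehand, but that bound left out the spread across sites, so shared flanks are not excluded.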
